A study of Mus musculus with 27 samples.

How the data were processed

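RNA was sequenced from 27 cultures of primary mouse cells. The labels name 3 cell types, namely microglia, bone marrow-derived macrophages (BMDM) and hepatocytes, and 3 treatments of each, with 3 libraries in every one of the 9 groups. Per the labels' protocols, microglia were shaken off mixed glial cultures, BMDM were differentiated from bone marrow with the growth factor M-CSF, and hepatocytes were plated on collagen. Treatments lasted 24 h in serum-free medium and consisted of an ethanol vehicle, 10 µM 24(S)-saringosterol or 1 µM of a synthetic compound. The labels spell the synthetic compound 3 ways (GW3596, GW3964 and GW3965), and it is called GW here; GW3965 is known as a synthetic agonist of the liver X receptors (LXR). Microglia and BMDM were treated in a DMEM/F12-based medium with M-CSF, insulin, transferrin, selenite and albumin, and hepatocytes in a Williams' E-based medium without these additions, so that treatment medium and cell type cannot be separated between hepatocytes and the other cells. The labels do not say whether the 3 replicates of a group came from separate animals or separate cultures, and p-values then measure only the spread between these libraries.

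Per the labels' protocols, RNA was isolated on columns and libraries were made with an oligo-dT primed SMARTer Ultra Low kit. Reads were demultiplexed with bcl2fastq, aligned with STAR 2.5.1a to the build GRCm38 and counted per gene with featureCounts 1.4.6-p5 of the Subread package, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. Genes that overlap another gene, antisense genes and members of families with near-identical copies (such as the Scd, Mup, Ifit and immunoglobulin genes, and the small RNA gene Snord13) are therefore uncertain. The authors deposited whole read counts per gene for each library, together with CPM, FPKM and TPM values. The deposited CPM values equalled the counts scaled to each library's total, the deposited TPM values equalled those of the series table, and the base of the authors' FPKM values is not stated. Tests used only the deposited counts. The files held 55487 gene identifiers, each with a symbol. The series table had 55774 lines because 168 identifiers stood on several identical lines, of which 1 was used. No count differed between the table of the series and the files of single libraries. Coordinates are those of the files on GRCm38; 55227 of the identifiers were found in the GENCODE M21 annotation, and 99.4% of these had the same gene span there.

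Total counts per library lay between 30295862 and 41040268. A count of 0 allows up to 3 counts, which is 0.073 to 0.099 CPM in these libraries. This floor covers counting error only, because reads amplified without molecular identifiers are not independent molecules. All 27 pairs of replicates within a group differed by more than sampling noise (chi-square per degree of freedom 3.77 to 37.43), and no pair of libraries was identical.

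Each cell type was fitted on its 9 libraries with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr were kept (16065 in microglia, 15416 in BMDM and 16098 in hepatocytes), TMM scaling was applied, and the quasi-likelihood F test with robust dispersion was run for saringosterol against vehicle, GW against vehicle and saringosterol against GW. A gene was called at an adjusted p under 0.05 after Benjamini-Hochberg adjustment over all genes tested, which is what "edgeR adjusted p" stands for in the text. The common biological coefficient of variation was 0.067 in microglia, 0.113 in BMDM and 0.065 in hepatocytes. Differences in response between cell types were tested as interaction contrasts in 1 fit of all 27 libraries (18979 genes). That fit gives each gene 1 dispersion for all cell types, so the counts for different pairs of cell types do not rank them. CPM values of single genes are given on TMM-scaled library sizes as mean ± SD with n = 3 per group, sums over marker lists and values of single libraries on plain totals, and log2 fold changes with their standard error (SE). A prior count of 2 entered log CPM values for principal components.

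Before the data were examined, 22 pathway lists and 13 marker lists were fixed (397 genes in all, every one found in the files). Lists with at least 4 tested members were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over all lists of a comparison. The camera test was repeated with the correlation estimated from the data; an adjusted p "with an estimated correlation" comes from that test. The fry test was run beside them. Counts of members that rose or fell are given over all genes tested and, where it differs, adjusted over the list alone beside it; where none stands beside, the count adjusted over the list alone was the same. Counts for differences between cell types and for the run without replicate 3 are over all genes tested. A list is called only by the preset camera test unless stated otherwise.

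Genes named in the text were taken by a rule that was also fixed before the data were examined. For each comparison with vehicle it takes the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in one group and no overlap of CPM between the groups, leaving out predicted genes and pseudogenes. It takes 5 of each for saringosterol against GW, and 4 of each for a difference between cell types, where overlap was allowed. Groups of 3 against 3 fail to overlap by chance for 10% of genes. The rule adds up to 4 members of each described list with the smallest adjusted p and a fixed set of genes of lipid handling and inflammation whatever their result, of which Abca1, Abcg1, Srebf1, Mylip, Apoe, Scd1, Fasn, Il1b, Tnf and Ccl2 are given. Some genes the rule takes are not reported here. Any other gene is said to have been chosen after its values were seen.

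Comparisons against the same 3 vehicle libraries share their chance values, so the correlation of both compounds' fold changes was set beside 20 simulations of unchanged groups against shared controls. The steps were tested on simulated counts with 200 changed genes. For saringosterol against vehicle, log2 changes of 0.5, 1 and 2 were drawn. Recovered were 59.7%, 80.6% and 95.5% in microglia, 55.2%, 79.1% and 92.4% in BMDM and 71.6%, 95.5% and 100% in hepatocytes. Unchanged genes made up 6%, 3.2% and 7.3% of the calls. For the saringosterol interaction of microglia with hepatocytes the shares were 37.3%, 79.1% and 98.5%, with 4% of the calls unchanged genes. These shares hold for the genes drawn and may differ for genes with low counts.

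The alternatives tried were size factors by relative log expression (RLE), no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, DESeq2 1.42.0, limma-voom with sample quality weights, a fit of only the libraries compared, a minimum log2 change of 1, and leaving out each library in turn. The gene lists of BMDM and of differences from BMDM without saringosterol replicate 3, and differences between cell types from each cell type's own standard errors, were added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures.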

Results

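The series profiled polyadenylated RNA in 3 kinds of primary mouse cell after 24 h with an ethanol vehicle, 10 µM 24(S)-saringosterol or 1 µM of the synthetic compound called GW here, with 3 libraries in each of the 9 groups. Saringosterol is a plant and algal sterol, and GW3965, one of the spellings the labels use for the synthetic compound, is a known agonist of LXR, nuclear receptors that sense oxidised sterols. The series title asks how the phytosterol affects lipid and inflammatory genes and whether this depends on the cell type. The compounds were given at different doses, so their values stand side by side at 10 µM and 1 µM and not at a matched dose. Libraries held 30295862 to 41040268 counts in genes.

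Identity markers set hepatocytes apart. Macrophage markers summed to 36300 ± 1110 CPM (SD, n = 3) in vehicle-treated microglia, 26300 ± 819 CPM in BMDM and 355 ± 16.1 CPM in hepatocytes. Homeostatic microglia genes summed to 1560, 2250 and 84.1 CPM in turn. The liver secretory gene Alb (albumin; chromosome 5, 90460897 to 90476602) stood at 6890 ± 71.3 CPM in vehicle-treated hepatocytes. In microglia the first principal component held 34.3% of the variance, and the 3 GW libraries lay at -38.7 to -34.9, the saringosterol libraries at 14.5 to 16.6 and the vehicle libraries at 21.5 to 22.2. The first component held 22.7% in BMDM and 17.3% in hepatocytes.

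**Figure D1:**
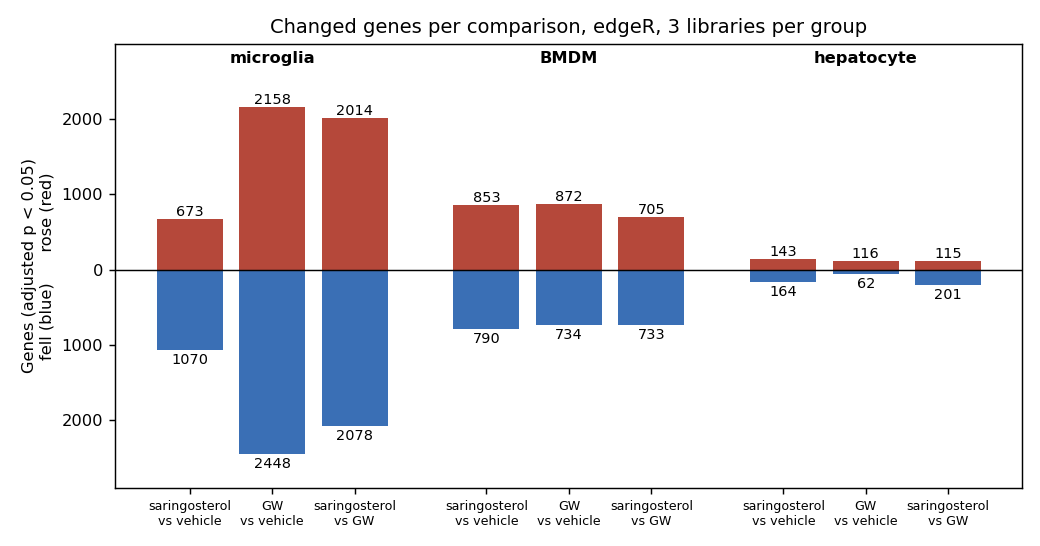
Numbers of genes called higher or lower (edgeR quasi-likelihood test, adjusted p under 0.05) for each comparison in microglia, BMDM and hepatocytes, with 3 libraries per group. The largest count is 4606 genes for GW against vehicle in microglia, and the smallest is 178 genes for the same comparison in hepatocytes.

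In microglia, saringosterol raised LXR targets and lowered cholesterol synthesis genes. Abca1, the transporter that moves cholesterol out of the cell (ENSMUSG00000015243; chromosome 4, 53030787 to 53159895), stood at 2260 ± 97.8 CPM (SD, n = 3) against 691 ± 13.8 CPM in vehicle, a rise of 1.71 ± 0.03 (SE) on the log2 scale (edgeR adjusted p = 5.5e-25). Abcg1, another sterol transporter, rose from 332 ± 11.4 to 651 ± 16.8 CPM and the apolipoprotein gene Apoc1 from 7.82 ± 0.596 to 22.5 ± 1.7 CPM. Apoe, which carries lipid between brain cells, rose from 8580 ± 359 to 11100 ± 189 CPM. Of 16 tested LXR targets 14 rose and 1 fell, with the same counts adjusted over the list alone and a median log2 change of 0.65 (camera adjusted p = 1e-04 with an estimated correlation). Of 20 cholesterol synthesis genes 19 fell and none rose (median -0.84, camera adjusted p = 0.00044 with an estimated correlation). Cyp51, the lanosterol demethylase (ENSMUSG00000001467; chromosome 5, 4081145 to 4104746), fell by 1.42 ± 0.05 on the log2 scale, from 80.9 ± 4.07 to 30.3 ± 1.48 CPM (edgeR adjusted p = 1.6e-17). Fdft1 (squalene synthase) fell from 20.3 to 7.19 CPM.

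Fatty acid genes of saringosterol-treated microglia moved both ways. Of 14 tested fatty acid synthesis genes 7 rose and 4 fell (median 0.32, camera adjusted p = 0.047 with an estimated correlation). The desaturase Scd1 (ENSMUSG00000037071; chromosome 19, 44394455 to 44407879) rose from 5.25 ± 0.301 to 14 ± 1.09 CPM, Scd2 from 569 to 1330 CPM and Fasn, the fatty acid synthase, from 91.7 ± 2.66 to 126 ± 8.85 CPM. By contrast, the desaturase Fads2 fell from 20 to 10.6 CPM. The master regulators split likewise, with Srebf1 rising from 89.3 to 145 CPM and Srebf2 falling from 122 to 73.5 CPM. The lipid droplet gene Plin2 fell from 1690 to 1010 CPM.

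Immune genes of saringosterol-treated microglia also changed. All 17 tested interferon-stimulated genes fell (median -0.84, camera adjusted p = 0.025 with an estimated correlation). The RNA sensor Ddx58 fell from 175 ± 4.41 to 114 ± 5.69 CPM, the signalling gene Stat2 from 235 to 129 CPM and Ifi44 from 20.5 to 8.56 CPM. The interleukin-1 genes went opposite ways. Il1b (ENSMUSG00000027398; chromosome 2, 129364570 to 129371139) fell by 2.09 ± 0.17 on the log2 scale, from 11.8 ± 1.83 to 2.76 ± 0.86 CPM (edgeR adjusted p = 7.8e-10). Il1a (ENSMUSG00000027399; chromosome 2, 129299610 to 129309972) rose by 1.80 ± 0.08, from 10.6 ± 0.959 to 36.9 ± 2.58 CPM (edgeR adjusted p = 2.4e-16). The chemokine Ccl2 rose from 69.1 ± 4.7 to 95.5 ± 4.61 CPM. Tnf stood at 20 ± 1.81 against 20.8 ± 1.74 CPM (edgeR adjusted p = 0.78). Of 18 inflammatory cytokines and chemokines 3 rose and 3 fell (4 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.77 with an estimated correlation). Its median of -0.05 and its upward test direction differ in sign. Of 11 homeostatic microglia genes 1 rose and 5 fell (2 and 6 adjusted over the list alone, median -0.55, camera adjusted p = 0.015 with an estimated correlation). Among them the fractalkine receptor Cx3cr1 fell from 46.3 ± 3.92 to 16.2 ± 3.29 CPM and the growth factor receptor Csf1r from 1370 ± 20.8 to 1040 ± 49.5 CPM.

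In all, edgeR called 1743 of 16065 genes for saringosterol against vehicle in microglia, 673 higher and 1070 lower, of which 38 and 71 changed at least 2-fold. Of 15 cell cycle genes 8 rose and none fell (12 rose adjusted over the list alone, median 0.29, camera adjusted p = 0.053 with an estimated correlation). Top2a, a topoisomerase of dividing cells, rose from 22.6 ± 1.05 to 30.1 ± 2.45 CPM. Astrocyte markers summed to 33.4 ± 3.62 CPM against 48.0 ± 1.64 CPM in vehicle (0 of 7 higher and 2 lower, camera adjusted p = 0.3 with an estimated correlation). In BMDM libraries, which come from bone marrow, this list summed to 15.7 to 50.2 CPM. Its sum need not stem from astrocytes, and its source was not tested. Macrophage markers summed to 36500 ± 252 against 36300 ± 1110 CPM.

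**Figure D2:**
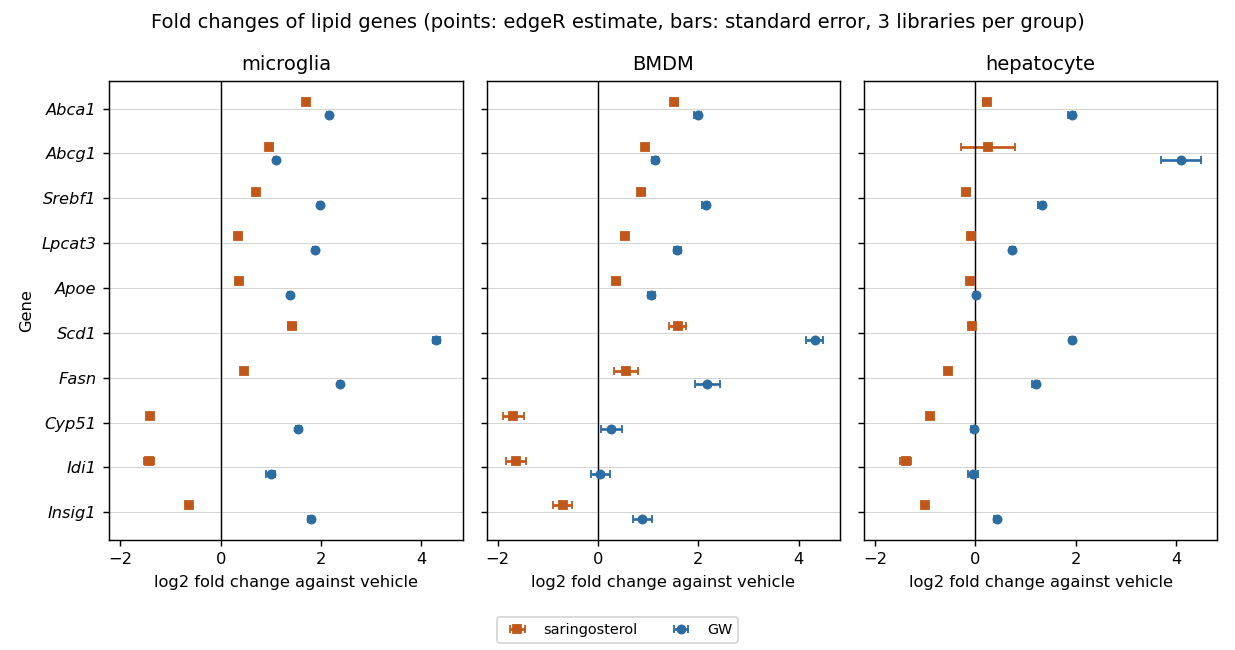
Log2 fold change against vehicle of 10 lipid genes for saringosterol (squares) and GW (circles) in microglia, BMDM and hepatocytes, with the edgeR estimate as the point and its standard error as the bar (3 libraries per group). Abca1 lies at 1.71 for saringosterol and 2.16 for GW in microglia and at 0.22 and 1.92 in hepatocytes.

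GW, at 1 µM, raised LXR targets, fatty acid synthesis and cholesterol synthesis genes together in microglia. Scd1 rose by 4.30 ± 0.07 (SE) on the log2 scale, from 5.25 ± 0.301 to 103 ± 2.43 CPM (SD, n = 3, edgeR adjusted p = 1.3e-27). Fads2 rose from 20 ± 0.42 to 173 ± 11 CPM, Fasn from 91.7 ± 2.66 to 478 ± 9.08 CPM and Srebf1 from 89.3 to 351 ± 3.28 CPM. Abca1 reached 3090 ± 55.9 CPM, a rise of 2.16 on the log2 scale, and Apoe rose from 8580 ± 359 to 22200 ± 490 CPM. Of 16 LXR targets 15 rose (16 adjusted over the list alone, median 1.24, camera adjusted p = 9.7e-05 with an estimated correlation). Of 14 fatty acid synthesis genes 13 rose (14 adjusted over the list alone, median 1.2, camera adjusted p = 0.00012 with an estimated correlation). All 20 cholesterol synthesis genes rose (median 0.99, camera adjusted p = 0.0021 with an estimated correlation). So did 6 of 6 genes of the list of sterol uptake and feedback on SREBP, the transcription factors that Srebf1 and Srebf2 encode (median 0.78, camera adjusted p = 0.0025 with an estimated correlation). Cyp51 rose to 236 ± 15.6 CPM. Of 11 genes of fatty acid oxidation and PPAR targets 9 rose (10 adjusted over the list alone, camera adjusted p = 0.0045 with an estimated correlation).

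Inflammatory, interferon and cell cycle genes fell with GW in microglia. Of 18 inflammatory genes 13 fell and 1 rose (15 and 1 adjusted over the list alone, median -1.44, camera adjusted p = 0.041 with an estimated correlation). Il1b fell by 3.13 ± 0.19 on the log2 scale to 1.33 ± 0.0296 CPM (edgeR adjusted p = 1.9e-13). Acod1, the itaconate enzyme (ENSMUSG00000022126; chromosome 14, 103046977 to 103056573), fell from 81.6 ± 1.38 to 9.78 ± 0.537 CPM and the chemokine Ccl2 from 69.1 ± 4.7 to 30.9 ± 0.659 CPM. Il1a rose from 10.6 to 43.4 CPM. All 17 interferon-stimulated genes fell (median -1.48, camera adjusted p = 0.025 with an estimated correlation). Of 15 cell cycle genes 13 fell and 1 rose (median -0.86, camera adjusted p = 0.025 with an estimated correlation). Mki67, a proliferation marker, fell from 17.7 ± 0.706 to 8.22 ± 0.531 CPM. Of 9 immediate early genes 7 fell and 1 rose (camera adjusted p = 0.029 with an estimated correlation). Homeostatic genes were split, 4 of 11 rising and 3 falling (camera adjusted p = 0.23 with an estimated correlation). The purine receptor P2ry12 rose from 11.3 ± 1.32 to 20.9 ± 1.83 CPM. The growth factor Csf1 fell from 91.4 ± 7.31 to 16.4 ± 0.619 CPM. It was 1 of 6 falling genes of the 16 of disease-associated microglia, of which 8 rose (9 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.77 with an estimated correlation).

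The largest log2 rise with GW in microglia by the rule for named genes was that of Ighm, the immunoglobulin mu constant region (ENSMUSG00000076617; chromosome 12, 113418558 to 113422730), from 0.367 ± 0.211 to 28.1 ± 3.48 CPM (6.23 ± 0.43, edgeR adjusted p = 1.7e-05), in a region of many similar genes. In total edgeR called 4606 of 16065 genes, 2158 higher and 2448 lower, of which 193 and 476 changed at least 2-fold. The 10 most counted genes held 19.8% of GW microglia counts against 17.8% in vehicle. Astrocyte markers summed to 65.7 ± 2.24 CPM against 48.0 ± 1.64 CPM in vehicle (2 of 7 higher, 3 adjusted over the list alone, camera adjusted p = 0.5 with an estimated correlation).

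Set directly against each other in microglia, 10 µM saringosterol and 1 µM GW differed in lipid, inflammatory and cell cycle lists, and edgeR called 4092 genes, 2014 higher and 2078 lower with saringosterol. All 20 cholesterol synthesis genes were lower with saringosterol (median -2.14, camera adjusted p = 8.3e-05 with an estimated correlation). So were 13 of 14 fatty acid synthesis genes (median -1.08) and 12 of 16 LXR targets (median -0.47, camera adjusted p = 0.00068 with an estimated correlation). Abca1 differed by -0.45 ± 0.034 (SE, log2), Abcg1 differed by -0.13 ± 0.035 (edgeR adjusted p = 0.0051) and Cyp51 by -2.96, at 30.3 against 236 CPM. Of 18 inflammatory genes 14 were higher with saringosterol and 1 was lower (15 and 1 adjusted over the list alone, median 1.22, camera adjusted p = 0.017 with an estimated correlation). Cxcl2, a neutrophil chemokine, stood at 17.6 ± 2.38 against 2.54 ± 0.673 CPM and Acod1 at 64.3 ± 1.72 against 9.78 ± 0.537 CPM. Of 15 cell cycle genes 14 were higher and 1 lower (median 1.27, camera adjusted p = 0.0023 with an estimated correlation). Mki67 stood at 20.8 against 8.22 CPM. Interferon-stimulated genes were higher for 14 of 17 (14 higher and 1 lower adjusted over the list alone, median 0.61, camera adjusted p = 0.22 with an estimated correlation).

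**Figure D3:**
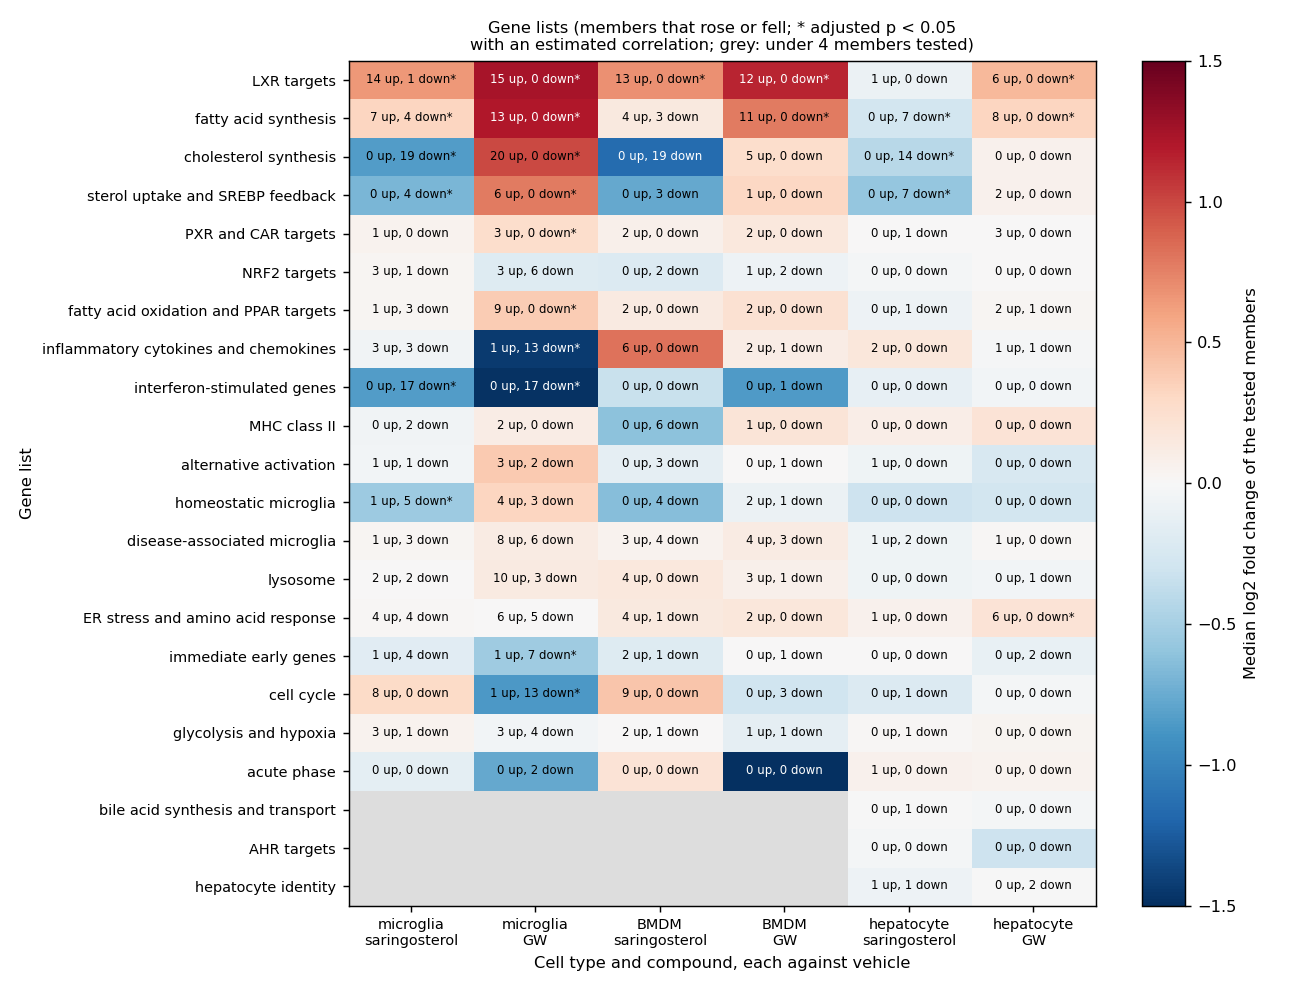
Median log2 fold change against vehicle of the tested members of each pathway list (colour, saturating at -1.5 and 1.5) for each compound and cell type, with the numbers of members that rose and fell printed in the field, an asterisk for an adjusted p under 0.05 with an estimated correlation, and grey for lists with under 4 tested members. Cholesterol synthesis has a median of -0.84 with saringosterol and 0.99 with GW in microglia, and the darkest field of BMDM, acute phase with GW at -1.68, has no called member.

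BMDM treated with saringosterol had higher LXR targets and lower cholesterol synthesis genes than vehicle-treated BMDM. Abca1 rose by 1.52 ± 0.07 (SE) on the log2 scale, from 549 ± 50 to 1570 ± 67 CPM (SD, n = 3, edgeR adjusted p = 1.6e-10). Abcg1 rose from 389 ± 10.6 to 745 ± 33.4 CPM and Scd1 from 19.5 ± 3.51 to 58.6 ± 8.49 CPM. Of 16 LXR targets 13 rose and none fell (14 adjusted over the list alone, median 0.68, camera adjusted p = 0.00029 with an estimated correlation). Of 20 cholesterol synthesis genes 19 fell (20 adjusted over the list alone, median -1.16, camera adjusted p = 0.054 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, fell from 291 ± 9.99 to 128 ± 11.8 CPM and Fdft1 from 27 ± 2.87 to 8.19 ± 1.32 CPM. Of 13 fatty acid synthesis genes 4 rose and 3 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.3 with an estimated correlation). Its call with the preset correlation ended without saringosterol replicate 3 (adjusted p = 0.052). Fasn stood at 96.0 ± 30.8 against 65.2 CPM (edgeR adjusted p = 0.21). Of 7 genes of MHC class II, which present antigen, 6 fell (7 adjusted over the list alone, median -0.61, camera adjusted p = 0.068 with an estimated correlation). H2-Ab1 (ENSMUSG00000073421; chromosome 17, 34257689 to 34269419) fell from 787 ± 65.2 to 516 ± 58.4 CPM. Of 16 inflammatory genes 6 rose (8 higher and 1 lower adjusted over the list alone, median 0.81, camera adjusted p = 0.2 with an estimated correlation). Without saringosterol replicate 3, 7 rose and 3 fell (median 0.29, camera adjusted p = 0.15 with an estimated correlation). The chemokine Ccl4 rose from 17.3 to 37.9 CPM. Of 15 cell cycle genes 9 rose (14 adjusted over the list alone, camera adjusted p = 0.14 with an estimated correlation).

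The largest log2 rises with saringosterol in BMDM by the rule were those of Il1a, from 0.865 ± 0.53 to 7.87 ± 3.55 CPM (3.16, edgeR adjusted p = 0.0064; 3.76 without vehicle replicate 1), and the NAD-consuming enzyme Cd38, from 1.87 to 15.3 ± 8.4 CPM. The scavenger protein gene Cd5l rose from 102 ± 6.52 to 324 ± 46.3 CPM. Il1b stood at 1.96 ± 2.83 against 2.15 CPM (edgeR adjusted p = 0.96; a log2 change of -2.71 and 1.1e-05 without saringosterol replicate 3) and Tnf at 9.64 against 9.33 CPM (edgeR adjusted p = 0.88). In total edgeR called 1643 of 15416 genes, 853 higher and 790 lower, of which 55 and 120 changed at least 2-fold. The count was 1008 without vehicle replicate 1 and 846 without vehicle replicate 2. Mitochondrial genes held 0.573 ± 0.057% of counts in vehicle, 0.399 ± 0.043% with saringosterol and 0.412 ± 0.042% with GW. Macrophage markers summed to 20800 ± 1190 CPM with saringosterol against 26300 ± 819 CPM in vehicle (2 of the list lower, camera adjusted p = 0.53 with an estimated correlation). Without saringosterol replicate 3, 5 were lower (camera adjusted p = 0.065 with an estimated correlation).

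Saringosterol replicate 3 of BMDM stood apart from replicates 1 and 2 in interferon-stimulated genes, and the result of that list rested on it. Their summed CPM was 279 and 320 in saringosterol replicates 1 and 2 and 1300 in replicate 3, against 548 to 787 in the vehicle libraries and 340 to 384 in the GW libraries. All 17 tested members were higher in replicate 3 than in replicates 1 and 2, by a median of 2.56 on the log2 scale. With all 3 libraries, edgeR called 0 of 17 members (median -0.33, camera adjusted p = 0.82 with an estimated correlation), DESeq2 called 0 and limma-voom 1 as lower, and 1 was lower at an unadjusted edgeR p under 0.05. Without replicate 3, a run added after the data were seen, 16 of 17 fell (median -1.47, camera adjusted p = 0.043 with an estimated correlation). In that run cholesterol synthesis fell for 20 of 20 (median -1.34, camera adjusted p = 0.001 with an estimated correlation). LXR targets rose for 14 of 16, and MHC class II fell for 7 of 7 (camera adjusted p = 0.013 with an estimated correlation). The same run called 1663 genes against vehicle, 707 higher and 956 lower.

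**Figure D4:**
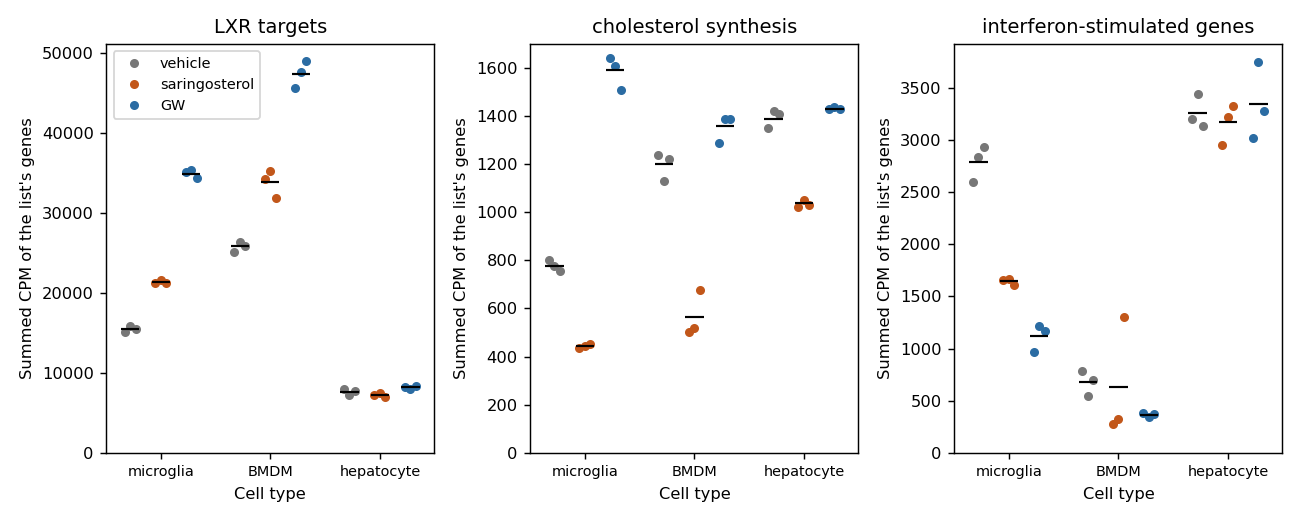
Summed CPM of LXR targets, cholesterol synthesis genes and interferon-stimulated genes in each of the 27 libraries (points) with the group mean (line), by cell type and treatment. Saringosterol replicate 3 of BMDM lies at 1300 CPM for interferon-stimulated genes, and replicates 1 and 2 lie at 279 and 320 CPM.

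GW raised LXR targets and fatty acid synthesis genes in BMDM as well. Of 16 LXR targets 12 rose (13 adjusted over the list alone, median 1.14, camera adjusted p = 3.3e-05 with an estimated correlation). Of 13 fatty acid synthesis genes 11 rose (12 adjusted over the list alone, median 0.78, camera adjusted p = 0.0031 with an estimated correlation). Scd1 rose by 4.32 on the log2 scale, from 19.5 ± 3.51 to 389 ± 32.6 CPM (SD, n = 3, edgeR adjusted p = 5e-06). Abca1 rose from 549 ± 50 to 2170 ± 173 CPM, Srebf1 from 92.9 ± 4.8 to 410 ± 14.1 CPM and Apoe from 15400 ± 628 to 32200 ± 1320 CPM. The phospholipid-remodelling enzyme Lpcat3 rose from 93.4 ± 10.3 to 279 ± 8.87 CPM. Of 20 cholesterol synthesis genes 5 rose (6 adjusted over the list alone, median 0.26, camera adjusted p = 0.56 with an estimated correlation). Lss, the lanosterol synthase, rose from 24.6 to 42.7 CPM. Tnf fell from 9.33 to 5.44 CPM, whereas Il1b was not called (edgeR adjusted p = 0.85). Of the inflammatory genes 2 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.82 with an estimated correlation). Interferon-stimulated genes had a median of -0.85 with 1 of 17 falling (camera adjusted p = 0.63 with an estimated correlation). Of 7 neutrophil and granulocyte precursor markers 5 fell (median -0.68, camera adjusted p = 0.069 with an estimated correlation). These markers summed to 42.1 ± 4.39 CPM against 68.9 ± 5.47 CPM in vehicle. S100a4, a calcium-binding protein gene, fell from 17.5 to 5.41 CPM and Fn1, fibronectin (ENSMUSG00000026193; chromosome 1, 71585520 to 71653200), from 80.9 to 33.9 CPM. In total edgeR called 1606 of 15416 genes, 872 higher and 734 lower. The count was 965 without GW replicate 2, 896 without GW replicate 3, 911 without vehicle replicate 1 and 909 without vehicle replicate 2.

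Between 10 µM saringosterol and 1 µM GW in BMDM, edgeR called 1438 genes, 705 higher and 733 lower with saringosterol, and 887 without GW replicate 3. All 20 cholesterol synthesis genes (median -1.43, camera adjusted p = 0.0071 with an estimated correlation) and 12 of 13 fatty acid synthesis genes (13 adjusted over the list alone, median -0.69) were lower with saringosterol. So were 11 of 16 LXR targets (12 lower and 1 higher adjusted over the list alone, median -0.40, camera adjusted p = 0.0042 with an estimated correlation) and all 7 MHC class II genes (median -0.80, camera adjusted p = 0.015 with an estimated correlation). Of 15 cell cycle genes 14 were higher (15 adjusted over the list alone, median 0.73, camera adjusted p = 0.02 with an estimated correlation). Birc5, a mitotic gene, stood at 26.9 against 14.8 CPM, and the replication gene Uhrf1 stood at 14.2 against 5.61 CPM. Abca1 differed by -0.46 ± 0.071 (SE, log2, edgeR adjusted p = 0.00025), Hmgcs1 stood at 128 against 269 CPM, and Il1a differed by -0.08 ± 0.389 (edgeR adjusted p = 0.94).

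In hepatocytes, saringosterol lowered cholesterol synthesis genes and no rise of the LXR target list was called. Idi1, the isopentenyl isomerase (ENSMUSG00000058258; chromosome 13, 8885501 to 8892451), fell by 1.39 ± 0.11 (SE) on the log2 scale, from 17.4 ± 2.12 to 6.61 ± 0.52 CPM (SD, n = 3, edgeR adjusted p = 7.2e-10). Insig1, which holds SREBP back, fell from 88.5 ± 2.4 to 43.9 ± 0.432 CPM and Cyp51 from 152 ± 8.5 to 81.1 ± 3.65 CPM. Of 20 cholesterol synthesis genes 14 fell and none rose (18 adjusted over the list alone, median -0.42, camera adjusted p = 4.4e-05 with an estimated correlation). So did 7 of 7 genes of sterol uptake and SREBP feedback (median -0.58, camera adjusted p = 4.7e-05 with an estimated correlation) and 7 of 16 fatty acid synthesis genes (8 adjusted over the list alone, median -0.28, camera adjusted p = 0.033 with an estimated correlation). Fasn fell from 72.2 ± 2.75 to 49.4 ± 3.4 CPM and Fads1 from 200 ± 6.06 to 139 ± 4.88 CPM. Of 18 LXR targets 1 rose (2 adjusted over the list alone, median -0.09, camera adjusted p = 0.97 with an estimated correlation). This was the ubiquitin ligase gene Rnf145, which rose from 24.0 ± 0.945 to 34.0 ± 4.24 CPM. Abca1 stood at 71.7 ± 9.41 against 61.7 ± 4.55 CPM, a log2 change of 0.22 ± 0.07 (edgeR adjusted p = 0.12). Abca1 passed without saringosterol replicate 1 (0.32, edgeR adjusted p = 0.0072) and without the low-count filter (0.23, edgeR adjusted p = 0.0069). Srebf1 stood at 103 against 116 CPM (edgeR adjusted p = 0.2, and 0.047 without vehicle replicate 2) and Scd1 at 896 against 939 CPM (edgeR adjusted p = 0.54).

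Other called genes of saringosterol-treated hepatocytes included immune and lipid-binding genes. Il1rn, the interleukin-1 receptor antagonist, rose from 13.4 ± 0.771 to 20.3 ± 2.28 CPM (edgeR adjusted p = 0.001), and the fatty acid binding gene Fabp5 fell from 19.1 to 11 CPM. The pheromone-carrier genes Mup4 and Mup18, members of a family of near-identical copies, stood at 6.35 against 2.72 CPM and 8.52 against 3.49 CPM, and Mup18 did not pass without vehicle replicate 3 (edgeR adjusted p = 0.071). Of 17 interferon-stimulated genes edgeR and DESeq2 called 0 and limma-voom 1 as lower (median -0.12, camera adjusted p = 0.68 with an estimated correlation), with 2 lower at an unadjusted edgeR p under 0.05. In total edgeR called 307 of 16098 genes, 143 higher and 164 lower, of which 9 and 7 changed at least 2-fold. The count was 203 without saringosterol replicate 1, 93 without saringosterol replicate 2, 140 without vehicle replicate 1, 803 without vehicle replicate 2 and 86 without vehicle replicate 3.

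GW raised LXR targets and fatty acid synthesis genes in hepatocytes. Scd1 rose by 1.93 ± 0.05 (SE) on the log2 scale, from 939 ± 47 to 3590 ± 321 CPM (SD, n = 3, edgeR adjusted p = 1.4e-20), and Abca1 by 1.92, from 61.7 ± 4.55 to 234 ± 6.9 CPM. Abcg1 rose from 0.139 ± 0.0296 to 2.43 ± 0.448 CPM, Srebf1 from 116 ± 9.65 to 291 ± 21.8 CPM and Fasn from 72.2 ± 2.75 to 166 ± 15.1 CPM. Of 18 LXR targets 6 rose (11 adjusted over the list alone, median 0.49, camera adjusted p = 1e-04 with an estimated correlation). Of 16 fatty acid synthesis genes 8 rose (11 adjusted over the list alone, median 0.32, camera adjusted p = 0.00021 with an estimated correlation). Of 20 cholesterol synthesis genes edgeR, DESeq2 and limma-voom each called 0 (median 0.06, camera adjusted p = 0.43 with an estimated correlation), and 3 were higher at an unadjusted edgeR p under 0.05. Apoe stood at 6580 against 6550 CPM (edgeR adjusted p = 0.99). Of 14 genes of the endoplasmic reticulum stress and amino acid response list 6 rose (9 higher and 1 lower adjusted over the list alone, median 0.20, camera adjusted p = 0.013 with an estimated correlation). The chaperone gene Hspa5 rose from 3140 ± 115 to 3830 ± 134 CPM and Herpud1 from 124 ± 1.94 to 166 ± 2.92 CPM. The gap junction gene Gjb1 fell from 117 to 80.7 CPM. In total edgeR called 178 of 16098 genes, 116 higher and 62 lower, and all 21 that changed at least 2-fold were higher. With limma-voom 288 were called, 157 higher and 131 lower.

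Between 10 µM saringosterol and 1 µM GW in hepatocytes, edgeR called 316 genes, 115 higher and 201 lower with saringosterol, with 205 without GW replicate 1 and 188 without GW replicate 3. Lower with saringosterol were 16 of 20 cholesterol synthesis genes (20 adjusted over the list alone, median -0.49, camera adjusted p = 3e-05 with an estimated correlation) and 14 of 16 fatty acid synthesis genes (15 adjusted over the list alone, median -0.65). So were 7 of 18 LXR targets (11 adjusted over the list alone, median -0.44, camera adjusted p = 5.9e-05 with an estimated correlation) and 7 of 7 genes of sterol uptake and SREBP feedback (median -0.65). Scd1 stood at 896 against 3590 CPM, Fasn at 49.4 against 166 CPM and Abca1 at 71.7 against 234 CPM, whereas Apoe differed by -0.12 ± 0.044 (SE, log2, edgeR adjusted p = 0.19). Il1rn was higher with saringosterol, at 20.3 ± 2.28 against 10.7 ± 0.946 CPM.

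Whether a response differed between cell types was tested as an interaction over all 27 libraries. For saringosterol, LXR targets responded more in microglia than in hepatocytes (9 of 18 members, median difference 0.58, camera adjusted p = 3.3e-06 with an estimated correlation). They also responded more in BMDM than in hepatocytes (11 of 18, median difference 0.68, camera adjusted p = 0.00017 with an estimated correlation). The log2 response of Abca1 was higher by 1.52 ± 0.11 (SE) in microglia than in hepatocytes (edgeR adjusted p = 2.1e-09) and by 1.34 ± 0.11 in BMDM than in hepatocytes. That of Scd1 was higher by 1.52 ± 0.17 and 1.70 ± 0.15. Between microglia and BMDM edgeR called 0 of 18 LXR targets (median difference -0.06, camera adjusted p = 0.87 with an estimated correlation) and DESeq2 1, and 2 responded less in microglia at an unadjusted edgeR p under 0.05. Abca1 differed by 0.18 ± 0.11 (edgeR adjusted p = 0.42). MHC class II fell less in microglia than in BMDM (3 of the list, median difference 0.48, camera adjusted p = 0.04 with an estimated correlation). Without BMDM saringosterol replicate 3, 6 of the list did so (median difference 0.65, camera adjusted p = 5.4e-05 with an estimated correlation), whereas the adjusted p was 0.053 to 0.1 without any 1 of 9 other libraries. Fn1 differed by 1.33 ± 0.21 and stood at 96.6 and 83.8 CPM in vehicle and saringosterol microglia and 80.9 and 27.7 CPM in BMDM.

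Other lists differed in their response to saringosterol with the preset correlation. Cholesterol synthesis genes had a lower response in BMDM than in hepatocytes (11 of 20, median difference -0.51, camera adjusted p = 0.1 with an estimated correlation). Without BMDM saringosterol replicate 3 this held for 15 of 20 (median difference -0.85, camera adjusted p = 2.9e-05 with an estimated correlation). In microglia their response was lower than in hepatocytes for 4 of 20 (median difference -0.34, camera adjusted p = 0.24 with an estimated correlation) and higher than in BMDM for 1 (median difference 0.23, camera adjusted p = 0.65 with an estimated correlation). The latter call ended without BMDM saringosterol replicate 1 (0.072 with the preset correlation). Without BMDM saringosterol replicate 3 it was higher than in BMDM for 6 of 20 (median difference 0.43, camera adjusted p = 0.0025 with an estimated correlation). Cell cycle genes had a higher response in BMDM than in hepatocytes (11 of 15, median difference 0.59, camera adjusted p = 0.1 with an estimated correlation), and 7 did without BMDM saringosterol replicate 3 (0.062; 0.0082 without replicate 1). Of 17 interferon-stimulated genes 1 had a lower response in BMDM than in hepatocytes (median difference -0.14, camera adjusted p = 0.82 with an estimated correlation), and the list was not called. Without BMDM saringosterol replicate 3 it was called, with 16 of 17 lower (median difference -1.31, camera adjusted p = 0.012 with an estimated correlation). Between microglia and BMDM the median difference of that list turned from -0.52 (camera adjusted p = 0.93 with an estimated correlation) to 0.55 without this library, with 3 of 17 higher in microglia and a call only with the preset correlation (1.4e-11, and 0.1 with an estimated one).

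For saringosterol edgeR called 382 genes between microglia and BMDM, 146 with a higher and 236 with a lower response in microglia (126 and 322 with RLE size factors), 224 between microglia and hepatocytes (172 and 52), and 1918 between BMDM and hepatocytes (1324 and 594). Opposite directions, both called, were found for 18, 1 and 8 of these genes. For microglia and BMDM the count was 681 without BMDM saringosterol replicate 1, 161 without microglia saringosterol replicate 3, 251, 204 and 651 without BMDM vehicle replicates 1, 2 and 3, and 200 without microglia vehicle replicate 3. For microglia and hepatocytes it was 148 without hepatocyte saringosterol replicate 2, 141 and 135 without microglia saringosterol replicates 1 and 2, and 131 without microglia vehicle replicate 2. For BMDM and hepatocytes it was 1220 without BMDM vehicle replicate 1.

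For GW, cholesterol synthesis genes responded more in microglia than in hepatocytes (18 of the list, median difference 1.08, camera adjusted p = 0.0022 with an estimated correlation). They also did so against BMDM (17 of the list, median difference 0.80, camera adjusted p = 0.065 with an estimated correlation, and 0.037 without BMDM vehicle replicate 2). Fatty acid synthesis genes responded more in microglia (9 members, median difference 0.79, camera adjusted p = 0.00036 with an estimated correlation) and in BMDM (10 members, median difference 0.39, camera adjusted p = 0.0059 with an estimated correlation) than in hepatocytes. LXR targets of microglia against hepatocytes had 7 higher and 2 lower responses (median difference 0.29, camera adjusted p = 0.00047 with an estimated correlation). The response of Apoe was higher by 1.39 ± 0.07 (SE, log2), and that of Abcg1 differed by -2.98 ± 0.23. Abca1 differed by 0.26 ± 0.11 (edgeR adjusted p = 0.17). EdgeR called 1843 genes between microglia and BMDM (841 higher and 1002 lower in microglia), 1649 between microglia and hepatocytes (958 and 691) and 899 between BMDM and hepatocytes (596 and 303), with opposite directions, both called, for 127, 12 and 7 genes.

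Calls shared between cell types were counted over the 13386 genes tested in all 3. With saringosterol 607 genes rose in microglia and 782 in BMDM, 217 of them in both, against 35.5 for independent lists, and 184 fell in both against 41. In hepatocytes 116 rose and 137 fell. Shared with microglia were 45 falls against 8.8 and 10 rises against 5.3. Shared with BMDM were 28 falls against 6.5 and 7 rises, about the 6.8 for independent lists. Falling in all 3 were 25 genes, which include Cyp51, Fdft1, Hmgcs1, Idi1, Lss, Msmo1 and Sqle of cholesterol synthesis, and Srebf2. Rising in all 3 were 5: Abcb4, Ccl2, Hbegf, Lipn and Rnf145. Both sets were named after their values were seen. Ccl2 did not pass in BMDM without vehicle replicate 1, 2 or 3 (edgeR adjusted p = 0.11, 0.11 and 0.078). In hepatocytes it did not without saringosterol replicate 1 or vehicle replicate 1 or 3 (0.18, 0.13 and 0.19). Abcb4 did not pass in BMDM without saringosterol replicate 1 or 2 or vehicle replicate 1 or 3 (0.055, 0.076, 0.12 and 0.095). In hepatocytes it did not without saringosterol replicate 2 (0.18). Hbegf did not pass in BMDM without saringosterol replicate 1 or 2 or vehicle replicate 1 or 2 (0.084, 0.083, 0.17 and 0.054). In hepatocytes it did not pass without saringosterol replicate 1, 2 or 3 or vehicle replicate 1 or 3 (0.11, 0.18, 0.063, 0.14 and 0.16), and Lipn did not without vehicle replicate 1 or 3 (0.092 and 0.059). With GW 420 genes rose in both microglia and BMDM against 115.9 for independent lists, and 38 rose in all 3 cell types, among them Abca1, Abcg1, Fasn, Lpcat3, Scd1 and Srebf1.

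Across genes, the log2 changes of saringosterol and GW against the same 3 vehicle libraries correlated with r = 0.412 in microglia, 0.509 in BMDM and 0.466 in hepatocytes (Spearman 0.393, 0.496 and 0.428). Genes are not independent replicates. Unchanged groups simulated against shared controls gave a median r of 0.494, 0.506 and 0.495 over 20 simulations. The covariance was 0.0747, 0.0973 and 0.0423 against a simulated 0.0351, 0.0459 and 0.033, a difference of 0.0396, 0.0515 and 0.00934. In microglia 432 genes rose and 670 fell with both compounds, against 90.4 and 163 for independent lists. In the same cells 54 rose with saringosterol and fell with GW and 109 did the reverse, against 102.6 and 143.7. In BMDM 318 rose and 250 fell with both, against 48.2 and 37.6, and in hepatocytes 13 and 3, against 1 and 0.6. The 3 vehicle libraries were not split between the compounds, and part of the excess in covariance and shared calls may come from the shared controls.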

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

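The tests of LXR targets and of B cell genes below, and the runs of gene lists without saringosterol replicate 3 of BMDM, were chosen only after the results were seen; the others were planned before. The counts, gene lists and single genes of differences between cell types stand here because the response to the same treatment differed between 2 cell types in a test of that difference itself. Counts over splits of the libraries are given for every comparison, and saringosterol replicate 3 of BMDM stands here because it lay apart from the other libraries of its group. Groups of 3 libraries were not examined for single outlying samples by a formal rule.

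Numbers of genes whose response differed were 382 (microglia against BMDM), 224 (microglia against hepatocytes) and 1918 (BMDM against hepatocytes) for saringosterol, and 1843, 1649 and 899 in the same order for GW (edgeR interaction test). For saringosterol between microglia and BMDM, 9 of 100 splits of the libraries, the real 1 included, gave a count as large, with a highest other count of 1428. Of the 100 splits 20 besides the real 1 kept the true groups of 1 cell type and mixed those of the other. Among splits that kept neither the highest count was 7. Every other split with a count as large kept the true groups of 1 cell type, and with them its response. The share of 9 in 100 therefore cannot decide whether chance gave the 382 genes. For the other 5 counts only the real split of 100 reached the real value (highest other 157, 846, 1832, 1410 and 227). Mixing treatments removes a response, so this cannot decide if responses differ. Splits that kept the true groups of 1 cell type gave up to 30, 846, 1832, 1410 and 227 genes, and those that kept neither up to 3, 39, 1, 1 and 3. The 157 came from the split that kept both and exchanged the treatments in 1 cell type. A count such as 1832 of 1843 with 1 cell type mixed shows that a response in the other alone can give most of the total. In the comparisons within a cell type 3 against 3 libraries make 10 splits, too few for a share under 0.05; only the real 1 reached the real count in each. The highest other counts were 1, 0 and 0 in microglia (against 1743, 4606 and 4092 genes for saringosterol against vehicle, GW against vehicle and saringosterol against GW), 0, 0 and 0 in BMDM (against 1643, 1606 and 1438) and 0, 5 and 1 in hepatocytes (against 307, 178 and 316).

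Gene lists whose response differed between cell types are given as the median difference of log2 changes, the first cell type minus the other. Those that passed camera with an estimated correlation for saringosterol were MHC class II at 0.48 for microglia against BMDM, LXR targets at 0.58, fatty acid synthesis at 0.23 and cell cycle at 0.49 for microglia against hepatocytes, and LXR targets at 0.68 for BMDM against hepatocytes. For GW they were LXR targets at 0.29, fatty acid synthesis at 0.79, cholesterol synthesis at 1.08, sterol uptake and SREBP feedback at 0.67 and fatty acid oxidation and PPAR targets at 0.28 for microglia against hepatocytes, and LXR targets at 0.16 and fatty acid synthesis at 0.39 for BMDM against hepatocytes. Their adjusted p lay from 3.3e-06 to 0.048. The call of MHC class II ended without any 1 of 9 libraries (adjusted p 0.053 to 0.1), that of cell cycle without any 1 of 10 (0.05 to 0.14) and that of fatty acid synthesis with saringosterol without any 1 of 8 (0.05 to 0.081). Other lists passed with the preset correlation and not with an estimated one. For saringosterol, microglia against BMDM, these were cholesterol synthesis at 0.23, NRF2 targets at 0.30, fatty acid oxidation and PPAR targets at -0.05, inflammatory genes at -1.06 (-0.06 without saringosterol replicate 3 of BMDM), lysosome at -0.13 and endoplasmic reticulum stress at -0.11. For microglia against hepatocytes they were cholesterol synthesis at -0.34, interferon-stimulated genes at -0.69, disease-associated microglia at 0.14, lysosome at 0.12 and immediate early genes at -0.07. For BMDM against hepatocytes they were fatty acid synthesis at 0.26, cholesterol synthesis at -0.51, MHC class II at -0.74, disease-associated microglia at 0.26, lysosome at 0.22, endoplasmic reticulum stress at 0.16 and cell cycle at 0.59. For GW the largest of these medians were cholesterol synthesis at 0.80, inflammatory genes at -0.98 and cell cycle at -0.62 for microglia against BMDM, inflammatory genes at -1.22 and interferon-stimulated genes at -1.53 for microglia against hepatocytes, and interferon-stimulated genes at -0.94 and fibroblast and stellate cell markers at -2.40 for BMDM against hepatocytes (-1.06 without GW replicate 3 of hepatocytes, where the call ended). With saringosterol, calls with the preset correlation ended without at least 1 library for cholesterol synthesis and fatty acid oxidation (microglia against BMDM), lysosome and immediate early genes (microglia against hepatocytes) and MHC class II, disease-associated microglia and endoplasmic reticulum stress (BMDM against hepatocytes), at an adjusted p of 0.051 to 0.22. Without saringosterol replicate 3 of BMDM, lists that newly passed with an estimated correlation for microglia against BMDM were cholesterol synthesis at 0.43, sterol uptake and SREBP feedback at 0.31, fatty acid oxidation and PPAR targets at -0.13, endoplasmic reticulum stress at -0.13 and macrophage markers at 0.33 (adjusted p = 0.0025, 0.024, 0.0098, 0.016 and 0.011). For BMDM against hepatocytes they were cholesterol synthesis at -0.85 and interferon-stimulated genes at -1.31 (adjusted p = 2.9e-05 and 0.012).

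Single genes are given by the log2 response to saringosterol of microglia minus that of BMDM (edgeR interaction test). It was 1.55 for Bex1, 1.43 for Fxyd2, 1.33 for Fn1, 1.22 for Gsta3 and -2.13 for Phgdh. It was -3.50 for Ccl7, -3.06 for Soat2 and -2.24 for Lbp, all low in vehicle BMDM (0.116, 0.224 and 0.2 CPM). For microglia minus hepatocytes it was 2.22 for Kif4, 1.97 for Car2 and 1.72 for Cd5l. For GW, microglia minus BMDM, it was 5.09 for Ighm, -3.51 for Cxcl2, -2.39 for Lbp, -2.30 for Traf1 and -2.26 for Spn, and for BMDM minus hepatocytes it was 4.34 for Lbp. Calls ended without single libraries for Bex1 (any of 7 libraries; adjusted p 0.052 to 0.092), Gsta3 (without replicate 3 of saringosterol or vehicle microglia; 0.086 and 0.083), Kif4 (without saringosterol hepatocyte replicate 1; 0.059) and Cd5l (without vehicle hepatocyte replicates 2 or 3 or vehicle microglia replicate 1; 0.071, 0.094 and 0.052). Without saringosterol replicate 3 of BMDM the difference was -2.88 for Ccl7 and -2.45 for Soat2, and without vehicle replicate 1 of BMDM it was -4.79 for Ccl7. Without vehicle replicate 3 of BMDM that of Lbp was -2.99 for saringosterol and -3.13 for GW in microglia minus BMDM, and 5.09 for GW in BMDM minus hepatocytes. Another 31 genes of the rule had a group mean at or under the floor, with no fold given.

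Genes fixed in advance also differed. For saringosterol, microglia minus hepatocytes, the log2 response differed by 1.52 for Abca1, 0.91 for Srebf1, 0.53 for Apoe, 1.52 for Scd1 and 1.04 for Fasn, and BMDM minus hepatocytes by 1.34 for Abca1, 1.09 for Srebf1, 0.52 for Apoe, 1.70 for Scd1, 1.15 for Fasn and 1.71 for Ccl2 (1.00 for Ccl2 without saringosterol replicate 3 of BMDM). For GW, microglia minus BMDM, the differences were 0.28 for Mylip, 0.30 for Apoe and -1.76 for Ccl2. Microglia minus hepatocytes they were -2.98 for Abcg1, 0.67 for Srebf1, 1.39 for Apoe, 2.38 for Scd1, 1.21 for Fasn and -1.17 for Ccl2, and BMDM minus hepatocytes -2.93 for Abcg1, 0.85 for Srebf1, 1.08 for Apoe, 2.41 for Scd1 and 1.01 for Fasn. Fasn for saringosterol in microglia against hepatocytes lost its call without any of 7 libraries (adjusted p 0.053 to 0.068), Mylip without any of 4 (0.055 to 0.12), and Ccl2 for GW in microglia against BMDM without GW BMDM replicates 1 or 2 or vehicle BMDM replicate 2 (0.057, 0.051 and 0.052).

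The list of LXR targets was called higher with saringosterol in microglia and BMDM and was not called in hepatocytes, where 1 of 18 members rose. Hepatocyte libraries that cannot show a change of this list are argued against by GW, with which the list was called against the same vehicle libraries (median 0.49, camera adjusted p = 1e-04 with an estimated correlation), while a smaller rise with saringosterol stays open. A sterol that did not act on hepatocytes at all is argued against by the 14 of 20 cholesterol synthesis genes that fell there. The treatment medium differs between hepatocytes and the other cells and cannot be told apart from the cell type, and no value here separates them. A candidate explanation is that the receptor response to saringosterol, at the 1 dose given, depends on the cell type, which stays open as a hypothesis.

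Ighm rose in microglia with GW from 0.367 to 28.1 CPM. B cells in the GW cultures are argued against by their markers, since the lymphocyte list summed to 0.0541 CPM in GW microglia against up to 0.317 CPM in a vehicle library, and the light chain gene Igkc stood at 0 CPM there. Reads of a neighbouring gene are argued against by the 36 annotated genes within 100 kb, of which 0 rose by at least 10% of the rise of Ighm. Reads from unannotated transcripts of the region or shared with similar immunoglobulin genes were not tested and stay open, next to a treatment-dependent transcript of the constant region in macrophage-like cells, which may account for the rise as a hypothesis.

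Saringosterol replicate 3 of BMDM stood apart in interferon-stimulated genes. A vehicle library under its label is argued against, because the library lay nearer to saringosterol replicates 1 and 2 at 72.6% of the 1661 genes tested with all 9 libraries among the 1663 called without it against vehicle, and a GW library because it did so at 78.6% of such genes (1404 among 1407). Cells of another type remain possible: 1 of 11 marker lists, that of Kupffer cells, lay above the other 8 BMDM libraries, at 63.3 against at most 36.0 CPM. BMDM express 4 of the Kupffer genes themselves, so cells of another type and a separate state of that culture cannot be told apart. No group of the design gives a biological explanation for 1 replicate, and none was tested.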

How the results depend on the processing

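The fits with each cell type's own standard errors were chosen only after the data were seen; the other alternatives were planned before. Counts of calls moved by over 1.5 times as follows. Also requiring a log2 change of at least 1 left 109, 669 and 542 genes in microglia (saringosterol against vehicle, GW against vehicle, saringosterol against GW), 175, 180 and 157 in BMDM and 16, 21 and 34 in hepatocytes, by construction a subset. With an estimated correlation camera called 6 lists for 10 (saringosterol) and 8 for 14 (saringosterol against GW) in microglia, 1 for 13, 2 for 10 and 6 for 11 in BMDM, and 3 for 8, 3 for 5 and 4 for 10 in hepatocytes; fry called 6 for GW in BMDM and 4 for saringosterol in hepatocytes. For GW in BMDM limma-voom called 2462 genes and the 6 libraries alone 2520, against 1606. For saringosterol in hepatocytes limma-voom called 1214, DESeq2 522 and no filter 491, against 307, and limma-voom called 288 for GW, against 178. In tests between cell types DESeq2 called 1090, 585 and 2892 genes for saringosterol (against 382, 224 and 1918) and 1498 for GW in BMDM against hepatocytes (899), and for saringosterol in microglia against hepatocytes the 18 libraries alone called 615 and own standard errors 591. The correlation of both compounds' changes was 0.470 in microglia and 0.541 in BMDM with DESeq2, and 0.533 in BMDM and 0.425 in hepatocytes with the CPM filter. The cause was not tested for these. No call that was kept or lost had the opposite sign. Genes near the floor of 0.073 to 0.099 CPM were not resolved under any of these settings.

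Same-numbered libraries of different groups correlated weakly, at -0.148 to 0.069 in microglia, -0.072 to 0.039 in BMDM and -0.025 to 0.111 in hepatocytes (9 pairs each, 1 of them above 0.1). Their median was -0.018 in microglia, -0.008 in BMDM and 0.026 in hepatocytes, against 0.0115, 0.001 and -0.01 for other pairs. A weak pairing by replicate number in hepatocytes can therefore not be excluded. With the replicate block edgeR called 782 genes for saringosterol in hepatocytes, 286 for GW and 544 for saringosterol against GW, and all of the 307, 178 and 316 genes called without it were among them; the other counts stayed within 1.5 times.

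Leaving out 1 library at a time gave 1240 to 1596, 3906 to 4183 and 3402 to 3790 genes in microglia, 846 to 1754, 896 to 1696 and 887 to 1475 in BMDM, and 86 to 803, 125 to 220 and 188 to 294 in hepatocytes. List calls were 10 to 12, 10 to 12 and 14 to 15 in microglia, 11 to 13, 8 to 10 and 10 to 13 in BMDM, and 7 to 8, 5 to 7 and 7 to 11 in hepatocytes. Between cell types the ranges were 161 to 681, 131 to 269 and 1220 to 2381 for saringosterol and 1362 to 1984, 1339 to 1480 and 606 to 1283 for GW. The correlation, without 1 vehicle library, was 0.474 to 0.505 in microglia, 0.568 to 0.605 in BMDM and 0.598 to 0.642 in hepatocytes. Single genes turned direction only where they were not called. Lists that were not called with all libraries turned too: without saringosterol replicate 3 of BMDM, interferon-stimulated genes went from -0.52 to 0.55 for microglia against BMDM and inflammatory genes from 0.99 to -0.08 for BMDM against hepatocytes (median differences for saringosterol). The genes were Tnf with saringosterol in microglia (-0.13 to 0.01, the highest without vehicle replicate 2) and in BMDM (-0.02 to 0.16, the lowest without saringosterol replicate 1), and Il1b with saringosterol in BMDM (-2.71 to 0.40, with 0.38 without saringosterol replicate 1 and 0.10 without vehicle replicate 1). In hepatocytes they were Abcg1 with saringosterol (-0.20 to 0.57) and Apoe with GW (-0.04 to 0.05, and 0 with limma-voom). Apart from these, 330 of the values for single genes, 44 of those for lists and 153 of those for differences between cell types lost their call when a library was left out, and 3036, 514 and 723 did not change.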

Other observations

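The runs without saringosterol replicate 3 of BMDM were chosen only after the results were seen, and the genes of the last 2 paragraphs were named only after their values were seen. In GW-treated microglia, members of the lysosome, oxidative stress and endoplasmic reticulum stress lists moved both ways, and none of these lists passed with an estimated correlation. Of 18 lysosome genes 10 rose and 3 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.035 with the preset correlation and 0.5 with an estimated correlation). The hexosaminidase gene Hexa rose from 1070 ± 36.1 to 1450 ± 21.9 CPM (SD, n = 3) and the protease gene Ctsl fell from 3810 ± 61.7 to 2730 ± 53.6 CPM. Of 10 targets of the oxidative stress regulator NRF2 3 rose and 6 fell (camera adjusted p = 0.56 with an estimated correlation), with Hmox1, the heme oxygenase, rising from 696 ± 18.7 to 1050 ± 51.7 CPM and Nqo1 falling from 23.4 ± 1.55 to 9.1 ± 1.21 CPM. Of 14 genes of the endoplasmic reticulum stress and amino acid response 6 rose and 5 fell (camera adjusted p = 0.58 with an estimated correlation), and Trib3 fell from 50.6 ± 2.27 to 23.2 ± 1.64 CPM. Of 10 alternative activation genes 3 rose and 2 fell (camera adjusted p = 0.24 with an estimated correlation). Among them Il1rn, the interleukin-1 receptor antagonist, fell from 855 ± 19.3 to 178 ± 1.42 CPM and the mannose receptor Mrc1 rose from 273 ± 16.8 to 403 ± 10.1 CPM. Abcc3, an export pump, rose from 83.7 ± 2.49 to 259 ± 5.2 CPM, 1 of 3 rising genes among 5 targets of the xenobiotic receptors PXR and CAR (camera adjusted p = 0.02 with an estimated correlation). It rose with saringosterol too, to 140 ± 9.49 CPM in microglia and from 104 ± 12.4 to 196 ± 18 CPM in BMDM, where GW gave 326 ± 32.6 CPM.

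With saringosterol in microglia, 4 of 6 genes of sterol uptake and SREBP feedback fell (5 adjusted over the list alone, median -0.68, camera adjusted p = 0.00082 with an estimated correlation). Immediate early genes fell for 4 of 9 and rose for 1 (camera adjusted p = 0.15 with an estimated correlation), with Fos falling from 70 ± 4.17 to 49.4 ± 0.995 CPM. Fatty acid oxidation and PPAR targets had 1 rise and 3 falls of 11, with a median of 0.03 and a downward test direction that differ in sign (camera adjusted p = 0.074 with an estimated correlation). Lists of glycolysis and hypoxia, NRF2 targets, lysosome, MHC class II, disease-associated microglia and the endoplasmic reticulum stress response had estimated-correlation p-values of 0.58, 0.53, 0.97, 0.77, 0.98 and 0.98. In BMDM saringosterol lowered 4 of 9 homeostatic microglia genes (median -0.64, camera adjusted p = 0.14 with an estimated correlation) and 3 of 9 alternative activation genes (4 adjusted over the list alone, median -0.14, camera adjusted p = 0.18 with an estimated correlation). Without saringosterol replicate 3, 4 homeostatic genes fell (median -1.12, camera adjusted p = 0.043 with an estimated correlation), and 5 alternative activation genes fell and 1 rose (median -0.41, camera adjusted p = 0.05 with an estimated correlation). Atf4, the amino acid response regulator, rose there from 63.3 ± 2.49 to 94.4 ± 5.97 CPM, in a list with 4 rises and 1 fall of 14 (6 and 1 adjusted over the list alone, camera adjusted p = 0.068 with an estimated correlation). Without replicate 3, 5 of that list rose and 1 fell (camera adjusted p = 0.043 with an estimated correlation).

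Liver function lists of hepatocytes moved little. Of 10 bile acid synthesis and transport genes 1 fell with saringosterol (camera adjusted p = 0.37 with an estimated correlation), and with GW edgeR, DESeq2 and limma-voom each called 0 (0.95), with 1 higher at an unadjusted edgeR p under 0.05. Of 15 hepatocyte identity genes 1 rose and 1 fell with saringosterol (0.31) and 2 fell with GW (0.45), among them the transcription factor Hnf4a, from 297 ± 15.1 to 223 ± 14.5 CPM. Of 15 PXR and CAR targets 1 fell with saringosterol (0.7) and 3 rose with GW (0.62), or 1 higher and 4 lower and 4 higher and 1 lower adjusted over the list alone, including Cyp2b10 from 55.8 ± 4.05 to 69.3 ± 4.19 CPM, which did not pass without GW replicate 2 (edgeR adjusted p = 0.057). Of 14 acute phase genes 1 rose with saringosterol (0.48; 3 higher and 1 lower adjusted over the list alone), and of 4 AHR targets edgeR, DESeq2 and limma-voom called 0 with either compound, as at an unadjusted edgeR p under 0.05 (0.79 and 0.49). Values in parentheses are camera adjusted p-values with an estimated correlation.

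Markers of other cell types are given as sums per group in the order vehicle, saringosterol and GW, and their source was not tested. Oligodendrocyte lineage markers summed to 147 ± 8.23 CPM in vehicle microglia, 128 ± 6.43 CPM with saringosterol (4 of 9 fell, camera adjusted p = 0.11 with an estimated correlation) and 151 ± 1.5 CPM with GW. Pdgfra fell with saringosterol from 5.55 ± 0.993 to 2.91 ± 0.612 CPM. Neuron markers summed to 4.69 ± 0.715, 3.42 ± 0.287 and 4.77 ± 0.459 CPM and dendritic cell markers to 3.44 ± 0.884, 4.66 ± 0.718 and 3.76 ± 0.445 CPM in the same order, and Kupffer cell markers to 294 ± 6.82, 358 ± 18.9 and 182 ± 5.04 CPM. In BMDM endothelial markers summed to 91 ± 5.18, 113 ± 11.9 and 145 ± 0.948 CPM. The scavenger receptor Stab2 of that list rose from 29 ± 1.45 to 52.9 ± 6.04 CPM with saringosterol and to 87.3 ± 2.37 CPM with GW. Fibroblast and stellate cell markers of BMDM summed to 4.19 ± 0.541, 2.12 ± 0.129 and 2.45 ± 0.547 CPM, and lymphocyte markers to 0.522 ± 0.225, 0.567 ± 0.0858 and 0.616 ± 0.196 CPM. Hepatocyte cultures held cholangiocyte markers at 184 ± 3.42, 184 ± 9.13 and 162 ± 2.87 CPM and erythroid markers at 25.4 ± 1.79, 19.8 ± 3.17 and 22.2 ± 0.762 CPM.

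Sex-linked genes were read in every cell type. In vehicle microglia Xist, the X-inactivation RNA, stood at 11.2 ± 0.838 CPM beside the Y-linked Ddx3y at 24.2 ± 2.84 CPM, whereas the mean of Xist was 0.0435 CPM in vehicle BMDM and 0.0164 CPM in vehicle hepatocytes, both under the floor of 3 counts, beside Ddx3y at 64.8 and 76.6 CPM. In microglia, with saringosterol, edgeR, DESeq2 and limma-voom called 0 of 5 sex-linked genes, and 1 was higher at an unadjusted edgeR p under 0.05. Ighm, which rose in GW microglia from near the floor, was expressed in vehicle BMDM at 113 ± 4.26 CPM, fell there to 58 ± 16.8 CPM with saringosterol (edgeR adjusted p = 0.035) and rose to 248 ± 4.05 CPM with GW (edgeR adjusted p = 0.019). The fall of Ighm did not pass without saringosterol replicate 2 or vehicle replicate 1, 2 or 3 (edgeR adjusted p = 0.054, 0.11, 0.099 and 0.083). Its rise did not pass without GW replicate 1, 2 or 3 or vehicle replicate 1 or 2 (edgeR adjusted p = 0.053, 0.067, 0.069, 0.079 and 0.078).

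In saringosterol-treated BMDM single genes of replicate 3 differed from replicates 1 and 2 by far more than those did from each other. The acute phase gene Saa3 stood at 0.466, 0.369 and 81.7 CPM in replicates 1, 2 and 3, the chemokine Ccl5 at 1.61, 1.55 and 48.1 CPM and the interferon regulator Irf7 at 12.7, 16.7 and 187 CPM.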
